A study of Homo sapiens with 3 samples.

How the data were processed

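Human embryonic kidney cells, called 293T in the sample titles and HEK293 in the growth text, were transfected with an empty vector, a plasmid carrying RET, or a plasmid carrying an OLFM4-RET fusion. RET is a receptor tyrosine kinase, and OLFM4 encodes olfactomedin 4, a secreted glycoprotein. Per the labels, total RNA was taken 48 h after transfection with a lipid reagent, and libraries were made with Illumina's standard protocols. The kit, its selection for or against poly(A) RNA, its handling of strand, the read length and the number of sequencing runs are not given in the sources used here. Each plasmid had 1 library, so the series held 3 libraries and no replicates.

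The authors deposited 1 table of raw counts per gene, with 58037 versioned Ensembl gene IDs and a column for each library, per the file headers. The counts are whole numbers that had not been normalised. The software is named only as cutadapt, HISAT2 and featureCounts, per the submitters' processing notes, which give no versions, roles or settings. The genome build and the annotation release are not given in the sources used here. The 3 columns were assigned to samples by the sample names in the labels, and 0 columns remained unassigned.

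Gene names came from a table of current symbols and otherwise from GENCODE release 29 on GRCh38. Of the 58037 IDs, 53647 were in that release with the same version, 57388 were in it when versions were ignored, and 41810 received a symbol. The authors' own release may therefore differ from the one used for names, gene types, transcript lengths and coordinates. A total of 16645 IDs had 0 counts in all 3 libraries. These included all 37 mitochondrial genes, which are listed at 0 in every library and were treated as not counted rather than as unexpressed, and the 45 Y copies of pseudoautosomal genes.

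Reads were counted in overlapping genes, including genes on opposite strands. RN7SK stands in the table under 2 IDs with identical counts, 2213481 in the vector library. GAPDH had 367924 counts there and the antisense gene AC006064.4 had 184631, and VIM had 96716 against 29645 for VIM-AS1. Counts of overlapping and antisense genes, and of near-identical copies such as HSPA1A and HSPA1B, HSPA6 and HSPA7, or the 7SL RNAs, are therefore uncertain, and overlaps of annotated exons are stated where such a gene is named.

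Libraries were scaled with the trimmed mean of M values (edgeR 4.0.16 in R 4.3.3), which gave factors of 1.07 for vector, 0.959 for RET and 0.975 for OLFM4-RET on top of the total counts. For each pair of libraries the log2 ratio of scaled counts was computed after adding 0.5 counts to each. A 95% interval was derived from the exact Clopper-Pearson interval of 1 gene's counts in the 2 libraries. These intervals cover counting error only, and they compare libraries rather than conditions. Several reads of the same molecule, where present, would make them too narrow even for that. With 1 library per plasmid, edgeR's quasi-likelihood test has no residual degrees of freedom, so no p-value was computed and no difference has a replicate check.

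A gene passed the size rule when its log2 ratio was at least 1 in absolute value, at least 1 of the 2 libraries had 50 or more normalised counts, and the counting interval left out 0. Genes with 50 or more normalised counts in at least 1 of the 2 libraries are called measured. A share or level of 0 counts was taken to allow up to 3 counts, which is 0.0301 CPM (counts scaled to library size) in the vector library, 0.0359 in RET and 0.0313 in OLFM4-RET. Ratios against a library at 0 are given against that floor in 1 library, and the other library's count enters them without its counting error.

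The comparisons, the size rule, 33 gene lists and the rule for naming genes were fixed before the data were examined. The lists covered signalling output (immediate early, ERK, STAT3, FOXO, serum response and YAP, NF-kB, interferon, TGF-beta and BMP, WNT, Notch), stress (unfolded protein response, ATF4, heat shock, p53, hypoxia), metabolism (glycolysis, cholesterol, fatty acids), the cell cycle (mitosis, DNA replication), RET biology (ligands and adaptors, neuroendocrine genes, other receptor tyrosine kinases), matrix remodelling, the intestinal epithelium, markers of other cell types (fibroblast, blood, epithelial) and quality (mitochondrially encoded genes, cytosolic ribosomal proteins, short RNAs without a poly(A) tail, replication-dependent histones, reference genes). A list was described by its members past the size rule, its median log2 ratio, and the percentile of that median among 10000 random lists of the same size drawn from 20 bins of mean expression. Percentiles describe these libraries, since genes of a list are not independent, and lists with fewer than 5 measured members received none.

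The genes named are RET and OLFM4, then, per comparison, the 10 highest and 10 lowest genes past the size rule with a symbol and 100 or more normalised counts, ranked by the interval bound nearer 0. Per list they are also up to 4 members past the rule with the largest log2 ratios, or up to 2 members with the most counts where none passed. Some of the genes this rule allows are not reported here, and others are named only where their later choice is stated.

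Both comparisons against vector use the same library. Their overlap was set against the overlap of independent lists of the same sizes and against 100 simulations of unchanged Poisson counts that shared the vector library. Transcript length was the longest GENCODE 29 transcript of a gene, and its relation to the log2 ratio was described over protein-coding genes with a mean of 200 or more normalised counts.

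The procedure was tested on simulated Poisson counts with 200 changed genes. These hold counting error only and no other variation between libraries. The numbers of unchanged genes that passed are therefore not an error rate for the real comparisons. In the simulation of RET against vector, over 19303 genes, all 50 genes changed 3-fold, all 50 changed 4-fold and all 50 changed 6-fold passed the rule, as did 1 of the 50 changed 1.5-fold and 3 unchanged genes, and 95.2% of intervals held the true ratio. In that of OLFM4-RET against vector, over 19311 genes, the same 3 sizes were recovered in full, none of the 50 genes changed 1.5-fold and 0 unchanged genes passed, and 95.1% of intervals held the true ratio. In that of OLFM4-RET against RET, over 19332 genes, 49 of the 50 genes changed 3-fold and all of those changed 4-fold or 6-fold passed, with 3 unchanged genes, and 95.0% of intervals held the true ratio. Among 200 random lists, 7.0% fell outside the central 95% of percentiles.

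Alternatives chosen in advance were DESeq2 1.42.0 size factors, total counts, upper quartile scaling, scaling without RET and OLFM4, minimums of 10, 200 or no counts, thresholds of 1.5-fold and 4-fold, intervals wholly beyond 2-fold, 5 added counts, and means in place of list medians. Alternatives added after the data were seen were removal of the length trend, protein-coding genes alone, genes whose exons overlap no other gene, scaling over protein-coding genes, and random lists of protein-coding genes. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.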

Results

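Gene expression was profiled by RNA sequencing in human embryonic kidney cells 48 h after transfection with empty vector, RET or OLFM4-RET plasmid, with 1 library each. HEK293 cells and their derivative 293T, which carries the SV40 large T antigen, are standard hosts for transfected genes. The series asks what the OLFM4-RET fusion does to gene expression, and the design sets it beside unfused RET and the empty vector. Total counts were 99539596 for vector, 83645289 for RET and 95878134 for OLFM4-RET. At least 1 count was found for 36717, 35045 and 36968 genes. The 10 gene IDs with the most counts took 10.97% of the vector library, 15.7% of the RET library and 15.3% of the OLFM4-RET library. They include RN7SK under both of its IDs, so the shares count it more than once. No difference described here has a replicate check, and "higher" and "lower" refer to single libraries.

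RET and OLFM4 were measured first, because the plasmids carry them. RET (ENSG00000165731.17) had 14.2 CPM, or counts scaled to library size, in the vector library (95% Poisson interval 13.5 to 15.0), 13688 in the RET library (13663 to 13713) and 8430 in the OLFM4-RET library (8412 to 8449). It ranked 6th among all gene IDs in the RET library and 9th in the OLFM4-RET library. These ranks count RN7SK under both of its IDs and, in the OLFM4-RET library, RPPH1 and the overlapping AL355075.4, whose counts are nearly equal. OLFM4 (ENSG00000102837.6) had 3.46 CPM with vector (3.10 to 3.84), 0.466 with RET (0.332 to 0.637) and 2704 with the fusion (2693 to 2714). In GENCODE 29 on GRCh38, the native RET gene lies on the plus strand of chromosome 10 at 43077027 to 43130351 and the native OLFM4 gene on the plus strand of chromosome 13 at 53028759 to 53052057. The build behind the counts is not stated, and counts per gene do not separate reads of the plasmid from those of the native gene or place a fusion junction. Both genes were high only in the libraries whose plasmids carry them per the labels. OLFM4 also passed the size rule between RET and vector, with 39 and 344 counts (log2 ratio -2.72, 95% counting interval -3.25 to -2.25). Neither of those plasmids is labelled as carrying OLFM4, and the cause of this difference was not tested. The RET count in the vector library was 0.124% of that in the RET library, and the OLFM4 counts in the vector and RET libraries were 0.133% and 0.0150% of that in the fusion library.

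The comparison of RET with vector asks what unfused RET did to expression. Interferon-stimulated genes, which cells induce when interferon signals, were far higher in the RET library, where all 29 members of the list passed the size rule, with a median log2 ratio of 4.14. OAS2, an antiviral enzyme activated by double-stranded RNA, had 470 counts in the vector library and 24546 in the RET library, a log2 ratio of 6.11 (95% counting interval 5.98 to 6.25). Immediate early genes, which growth factors induce without new protein synthesis, were also higher, with 14 of 28 measured members past the rule, and EGR1 went from 197 to 3520 counts (4.56, 4.36 to 4.78). The stress chaperone HSPA6, with 68 and 4246 counts, ranked highest by its interval when RET was left out (6.36, 6.03 to 6.74).

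In all, 861 of 19480 measured genes passed the size rule between RET and vector, 651 higher in the RET library and 210 lower. Of these, 475 of the higher genes and 50 of the lower genes were protein-coding. When total counts were used for scaling, the split was 518 higher and 334 lower, because that scaling moved the median of all measured genes to -0.15 from 0.01. Differences of 4-fold or more were found for 255 higher genes, and of 16-fold or more for 70.

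Among the interferon-stimulated genes, XAF1 (log2 ratio 5.72), the OAS-like gene OASL (5.62) and the type III interferon IFNL1 (5.62) had the largest ratios after OAS2. XAF1 overlaps the antisense gene PRAL (5.77) in its exons, so their counts cannot be separated. The antiviral GTPase MX2 (5.65) and the apolipoprotein APOL6 (5.74), outside the list, were among the 10 highest genes of the comparison, as was the pseudogene IFIT6P with 1 and 194 counts. The median of the interferon list lay above all 10000 random lists, at percentile 100. In the list of NF-kB and inflammatory genes, 7 of 13 measured members passed, all higher, with a median of 1.24 (percentile 100). They included the chemokines CXCL8 (3.26) and CCL2 (2.03), the cytokine gene IL1A (2.13) and the transcription factor IRF1 (2.93), which is also induced by interferon.

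The median of the immediate early genes was 0.89 (percentile 100), with ARC at 4.31, FOS at 3.60 and EGR2 at 3.43. Of the 26 measured genes of ERK output and feedback, 12 were higher and 0 lower, with a median of 0.76 (percentile 100). They included VGF (3.70), IL11 (2.91), the AP-1 subunit FOSL1 (2.82) and the ETS factor ETV4 (1.92), whose exons overlap DHX8. Of 12 measured STAT3 targets, SOCS3 (3.23) and SOCS1 (2.12), feedback inhibitors of cytokine receptors, passed the rule (median 0.46, percentile 99.99). Of 19 serum response and YAP targets, 4 were higher, namely CCN2 (1.80), ANKRD1 (1.61), CNN1 (1.23) and AXL (1.08), with a list median of 0.16 (percentile 97.26). None of 17 FOXO targets passed (median -0.10, percentile 5.27), and SESN3, the member with the most counts, had a ratio of -0.62.

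Of 27 genes of matrix remodelling and migration, 7 were higher and 0 lower. The metalloproteases MMP1 (3 and 205 counts, log2 ratio 6.28, 4.93 to 8.79), MMP13 (4.94), MMP3 (2 and 51 counts, 4.77, 3.15 to 8.16) and MMP10 (4.45) led the list. MMP1 and MMP3 share exonic sequence with the gene WTAPP1. The median of the list was 0.15 (percentile 98.09) and turned to -0.02 under total-count scaling. Of 15 TGF-beta and BMP targets, 2 were higher, including TGFBI (1.56), with a list median of 0.11 (percentile 89.86). SCG2 (1.34), GAP43 (1.25) and CHGB (1.18) were the 3 higher genes among 12 measured neuroendocrine genes (median 0.45, percentile 99.83). With a minimum of 200 counts 1 of them was higher and the median was 0.17, within the random lists (percentile 89.16), as was the mean (percentile 90.24). Among 22 other receptor tyrosine kinases, EPHA2 (1.10) and AXL passed (median -0.11, percentile 3.81), but with total counts neither did, at 0.94 and 0.92. None of 26 measured RET ligands, co-receptors and adaptors passed (median 0.01, percentile 46.88).

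Of 23 ATF4 targets, genes of amino acid supply and the integrated stress response, 11 were higher and 0 lower, with a median of 0.86 (percentile 100), and 7 were higher under total-count scaling. FGF21 (1.92), the phosphatase subunit PPP1R15A (1.60), the pseudokinase TRIB3 (1.60) and CHAC1 (1.48) had the largest ratios. Of 22 genes of the unfolded protein response, XBP1 (1.25) and HERPUD1 (1.14) passed, with a list median of 0.36 (percentile 100); under total-count scaling HERPUD1 (0.98) fell short. Of 17 heat shock genes, HSPA6 and HSPA1A (1.43) passed, with a median of 0.23 (percentile 99.77). None of 20 p53 targets (median 0.07, percentile 79.21) or 18 hypoxia targets (0.12, percentile 96.80) passed.

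No member passed in the lists of glycolysis (median -0.02 over 17 genes, percentile 16.08), cholesterol synthesis (-0.08 over 25, percentile 2.72), fatty acid synthesis (-0.22 over 12, percentile 0.08), mitosis (-0.18 over 26, percentile 0.00), DNA replication (0.06 over 26, percentile 70.94), WNT targets (-0.02 over 13, percentile 42.83), Notch targets (-0.05 over 9, percentile 28.48) or intestinal epithelium (-0.11 over 5, percentile 22.89). The proliferation marker MKI67 had a ratio of -0.75 and TOP2A one of -0.29, both short of the rule. Among markers of other cell types, 0 of 4 measured fibroblast genes passed. Of 2 measured blood cell genes the lysosomal protein CD68 did (2.87), with exons shared with neighbouring genes. Of 9 measured epithelial genes KRT14 passed, with 0 and 182 counts, 80.5-fold above the floor of the vector library (list median 0.41, percentile 99.87). XIRP1, an actin-binding protein of muscle, likewise had 0 and 176 counts and was 77.8-fold above that floor.

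Genes lower in the RET library had smaller differences, with 9 of 4-fold or more. Lowest by its interval was SULT6B1, with 303 counts in the vector library and 6 in the RET library (-5.14, -6.71 to -4.11), in exons shared with CEBPZOS. The long noncoding RNAs LINC00641 (-1.57), KCNQ1OT1 (-1.38, overlapping KCNQ1) and MIR600HG (-1.31, overlapping STRBP) were also among the 10 lowest. Among protein-coding genes, TNFRSF10D, a decoy receptor for the death ligand TRAIL, had 11561 and 3680 counts (-1.24, -1.30 to -1.19), and MAGED4B had a ratio of -1.47. NANOS1, which overlaps EIF3A, was at -1.33.

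Some quality lists differed between these libraries. All 10 measured short RNAs without a poly(A) tail had ratios above 0 (median 0.74, percentile 100), and their share of counts was 5.70% in the vector library, 7.95% in RET and 8.03% in OLFM4-RET. Replication-dependent histones had a median of -0.23 over 14 genes (percentile 0.01), 4 of them above 0. The median of 39 cytosolic ribosomal protein genes was 0.16 (percentile 99.17), and 0.10 (percentile 85.67) with the length trend removed. RPS29 stood apart at 4.36 (4.32 to 4.39), with 7012 and 108359 counts. Of 14 reference genes, B2M, the light chain of MHC class I, was higher (1.82), with a list median of 0.04 (percentile 45.67). None of the mitochondrially encoded genes was measured.

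The comparison of OLFM4-RET with vector asks what the fusion did. Growth factor response genes were higher in the fusion library, with 15 of 28 immediate early genes and 13 of 26 ERK output genes past the size rule and 0 lower in either list. EGR1 had 197 and 4780 counts (4.78, 4.58 to 5.0), and the ERK-inducible ETS factor ETV4 had 489 and 3055 (2.83, 2.69 to 2.97). The chaperones HSPA6 (7.01, 6.68 to 7.39) and HSPA1A (2.49, 2.46 to 2.51) and the protease MMP10 (5.10, 4.85 to 5.37) were higher too. Of 26 measured interferon-stimulated genes, only IFNL1 (13 and 65 counts, 2.47, 1.64 to 3.49) and OASL (1.18, 0.94 to 1.43) passed.

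In all, 615 of 19543 measured genes passed, 533 higher in the OLFM4-RET library and 82 lower, including 374 higher and 26 lower protein-coding genes. Scaling by total counts gave 432 higher and 151 lower, with the median of all measured genes moved to -0.14 from -0.01. There were 198 genes higher by 4-fold or more, and 45 by 16-fold or more.

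The immediate early list had a median of 1.15 and the ERK list one of 1.04, each at percentile 100. ARC (4.36), FOS (3.80), EGR2 (3.61), VGF (3.89), IL11 (3.59) and FOSL1 (3.18) had the largest ratios beside EGR1 and ETV4. SOCS3 (3.82) and the cytokine receptor gene OSMR (1.22, overlapping RICTOR) were the 2 of 12 measured STAT3 targets that passed (median 0.42, percentile 100). Of 20 serum response and YAP targets, 6 were higher, with ANKRD1 at 2.20, CCN2 at 2.19, CNN1 at 1.41 and AXL at 1.36 (median 0.18, percentile 99.16). Of 13 measured NF-kB and inflammatory genes, 8 were higher, among them CXCL8 (4.04), CCL2 (3.09), ICAM1 (2.08, overlapping antisense genes) and IRF1 (1.63), with a median of 1.10 (percentile 100).

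Matrix remodelling genes were higher for 10 of 27 members, with a median of 0.39 (percentile 100), or 0.20 with a minimum of 200 counts, led by MMP1 (3 and 302 counts, 6.62, 5.28 to 9.13), MMP3 (2 and 99 counts, 5.50, 3.93 to 8.88) and MMP10. Of 15 TGF-beta and BMP targets, 2 were higher, including TGFBI (2.11), with a median of 0.18 (percentile 99.19). EPHA2 (1.45) and AXL were higher and KDR (-1.06), a receptor for VEGF, was lower among 22 other receptor tyrosine kinases (median -0.11, percentile 5.44), though KDR fell short with the length trend removed (-0.97). GRB7 (1.13) passed among 26 RET ligands and adaptors (median 0.00, percentile 52.44) but not with total counts, and CHGA (1.41) and GAP43 (1.20) among 11 neuroendocrine genes (median 0.31, percentile 98.86). With a minimum of 200 counts 1 neuroendocrine gene passed and the median was 0.20, within the random lists (percentile 94.17), as was the mean (percentile 92.74).

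Of 17 heat shock genes, HSPA1B (1.61) passed beside HSPA6 and HSPA1A (median 0.33, percentile 100). Of 23 ATF4 targets, 6 were higher, including FGF21 (1.60), PPP1R15A (1.35), CHAC1 (1.19) and the amino acid transporter gene SLC7A5 (1.18), with a median of 0.62 (percentile 100). The glucose transporter gene SLC2A3 (1.04) was the 1 of 19 hypoxia targets to pass, and none passed with total counts and 2 with upper quartile scaling. None of the 22 unfolded protein response genes passed (median 0.13, percentile 98.46). The interferon list had a median of 0.32 (percentile 100). No gene passed in the lists of FOXO targets (median -0.10), p53 targets (-0.02), glycolysis (0.06), cholesterol synthesis (-0.16, percentile 0.08), fatty acid synthesis (-0.27, percentile 0.01), mitosis (-0.03, percentile 8.65), DNA replication (0.04), WNT targets (0.04), Notch targets (-0.04) or intestinal epithelium (-0.16).

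The plasminogen activator inhibitor gene SERPINB2 (97 and 4793 counts, 5.81), the overlapping SERPINB10 (5.76) and TM4SF1 (1 and 156 counts, 6.89, 4.97 to 12.79) were among the 10 highest genes. XIRP1, ATP1B4 and KRT79 had 0 counts in the vector library and were 98.7-fold, 54.6-fold and 43.6-fold above its floor. Of the markers of other cell types, KRT14 (36.4-fold above that floor), COL6A3 (7 and 102 counts, 3.96), CD68 (1.38) and CD14 (1.17) passed. The lower genes included the integrin subunit gene ITGA8 with 2907 and 1078 counts (-1.24, -1.35 to -1.14), the semaphorin receptor gene PLXNA4 (-1.05, and -0.86 with the length trend removed), TMEM132B (-1.61), NTM (-1.52), ITIH5 (-1.17) and the pseudogene HS6ST1P1 (-3.16). Among quality lists, short RNAs without a poly(A) tail had a median of 0.73 (percentile 100), and RNU5A-1 (1.41), SNORD3A (1.17) and RNU4-2 (1.12, and 0.99 with total counts) passed. Histones had a median of 0.26 (percentile 99.81), ribosomal protein genes one of 0.26 (percentile 100) and reference genes one of 0.07 (percentile 60.69), with no member past the rule.

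**Figure D1:**
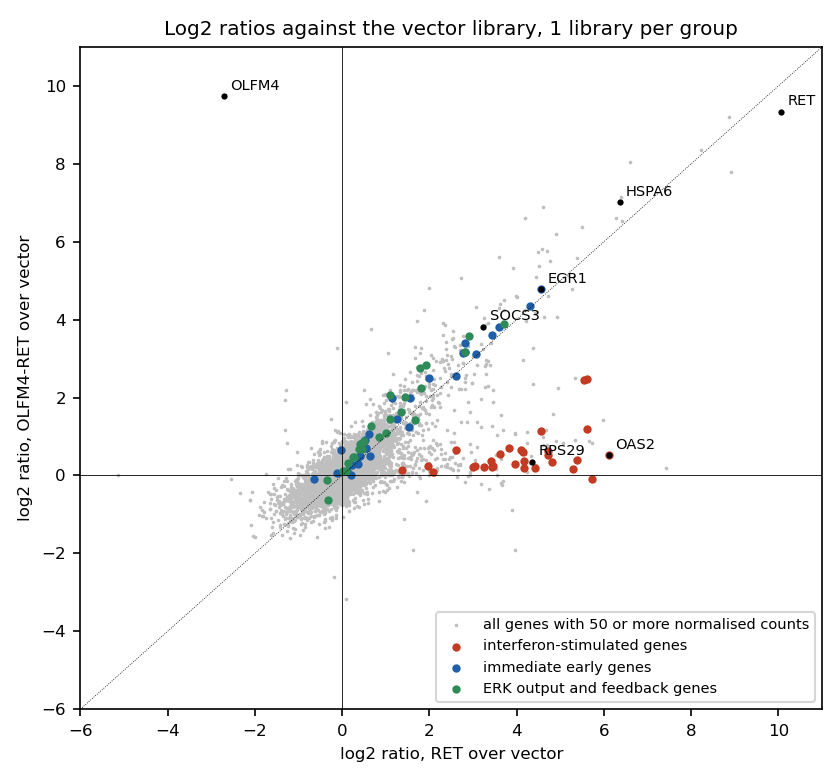
Each point is a gene with 50 or more normalised counts in at least 1 library, with its log2 ratio of RET over vector on the horizontal axis and of OLFM4-RET over vector on the vertical axis, 1 library per group, and the dotted line marks equal ratios. Interferon-stimulated genes such as OAS2 (6.11 with RET) spread along the horizontal axis, while immediate early genes such as EGR1 (4.56 and 4.78) and genes of ERK output lie near the dotted line.

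Both comparisons share the vector library. Among 19311 genes measured in both, 575 were higher with RET and 453 with OLFM4-RET, and 335 were higher in both, where independent lists of those sizes would share 13.5 and simulated unchanged libraries shared 0.0300 on average. Of 210 and 82 lower genes, 41 were shared, against 0.892 for independent lists and 0.0300 in simulation. Opposite directions were found for OLFM4 itself, for the pseudogene UBE2V1P2 (-1.31 with RET and 1.17 with the fusion) and for the 7SL pseudogene RN7SL5P (1.42 and -1.11). Across genes, which are not independent replicates, Pearson's r of the log2 ratios was 0.78, against 0.48 in simulation. The covariance was 0.198, against 0.00591 in simulation, a difference of 0.192. The simulation held counting error only, so any other deviation of the shared vector library adds to the excess over it. Part of the shared calls may come from the single vector library, which could not be split.

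The comparison of OLFM4-RET with RET asks where the fusion differed from unfused RET. The interferon-stimulated genes set the 2 libraries apart, with all 29 members lower in the fusion library, by a median log2 ratio of -3.42 (percentile 0.00). RSAD2, the antiviral enzyme viperin, had 37652 counts with RET, 1267 with OLFM4-RET and 1278 with vector. Its ratio between fusion and RET was -5.11 (-5.20 to -5.03), and its exons overlap the antisense gene CMPK2. IFIT2 had 55937, 2062 and 1779 counts (-4.98, -5.05 to -4.92). Growth factor response genes did not separate the libraries by the size rule, with 0 of 28 immediate early genes and 0 of 26 ERK output genes past it.

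In all, 342 of 19423 measured genes passed, 102 higher in the fusion library and 240 lower, including 53 higher and 183 lower protein-coding genes. With a minimum of 10 counts the majority turned, to 524 higher and 450 lower, as it did with no minimum (691 and 517) and at a 1.5-fold threshold (475 and 457). Among the 10 lowest were XAF1 (-5.81) with PRAL, OAS2 (-5.60), APOL6 (-4.91), MX2 (-4.78), OAS1 (-4.47) and OASL (-4.44). RPS29 was lower too (-4.01, -4.04 to -3.97), with 7858 counts in the fusion library, as were CD68 (-1.49), KRT14 (-1.14) and B2M (-1.31).

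The immediate early genes had a median of 0.19 and the ERK output genes one of 0.29, each above all random lists (percentile 100). Random lists were matched on mean expression but not on GC content. Across protein-coding genes, ratios in this comparison rose with the GC content of transcripts (Spearman's rho 0.22). Its part in small list medians of this comparison was not tested. Named after their values were seen, the ERK feedback genes DUSP6 (0.97, 0.87 to 1.08) and SPRY4 (0.97, 0.75 to 1.19) and the ETS factor ETV4 (0.91, 0.82 to 1.01) had the largest ratios of the ERK list and stopped short of the rule. RET itself had a ratio of -0.72 (-0.73 to -0.72). Its counts also depend on how much RET sequence each plasmid carries, so this ratio does not compare numbers of transcripts. Of 17 heat shock genes, HSPA1A was higher (1.06, 1.04 to 1.08), with a list median of 0.15 (percentile 100). The median was -0.31 over 22 genes of the unfolded protein response, -0.25 over 23 ATF4 targets and -0.18 over 20 p53 targets, each at percentile 0.00 and with no member past the rule; the mean of the p53 targets was within the random lists (percentile 6.33).

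In the NF-kB list, CCL2 was higher (1.06), and CSF1 (-1.37) and IRF1 (-1.31) were lower, with a median of 0.07 (percentile 95.41). SOCS1 (-1.70) was the 1 STAT3 target past the rule, MMP13 (3064 and 549 counts, -2.70) the 1 matrix remodelling gene and CHGB (-1.27) the 1 neuroendocrine gene. Mitotic genes had a median of 0.19 (percentile 100) and replication-dependent histones one of 0.55 (percentile 100), with the linker histone gene H1-2 at 0.74. Short RNAs without a poly(A) tail had a median of 0.02 (percentile 63.43). The genes highest in the fusion library had low counts in the other library, among them the trypsin inhibitor gene SPINK1 (27 and 163 counts, 2.35), SLC12A8 (2.37), TM4SF1 (2.29), COL6A3 (2.25), the protease inhibitor gene A2M (60 and 297 counts, 2.08) and the cytokine gene IL24 (68 and 320 counts, 2.01). SULT6B1 had 6 and 268 counts (5.15), against 303 with vector.

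**Figure D2:**
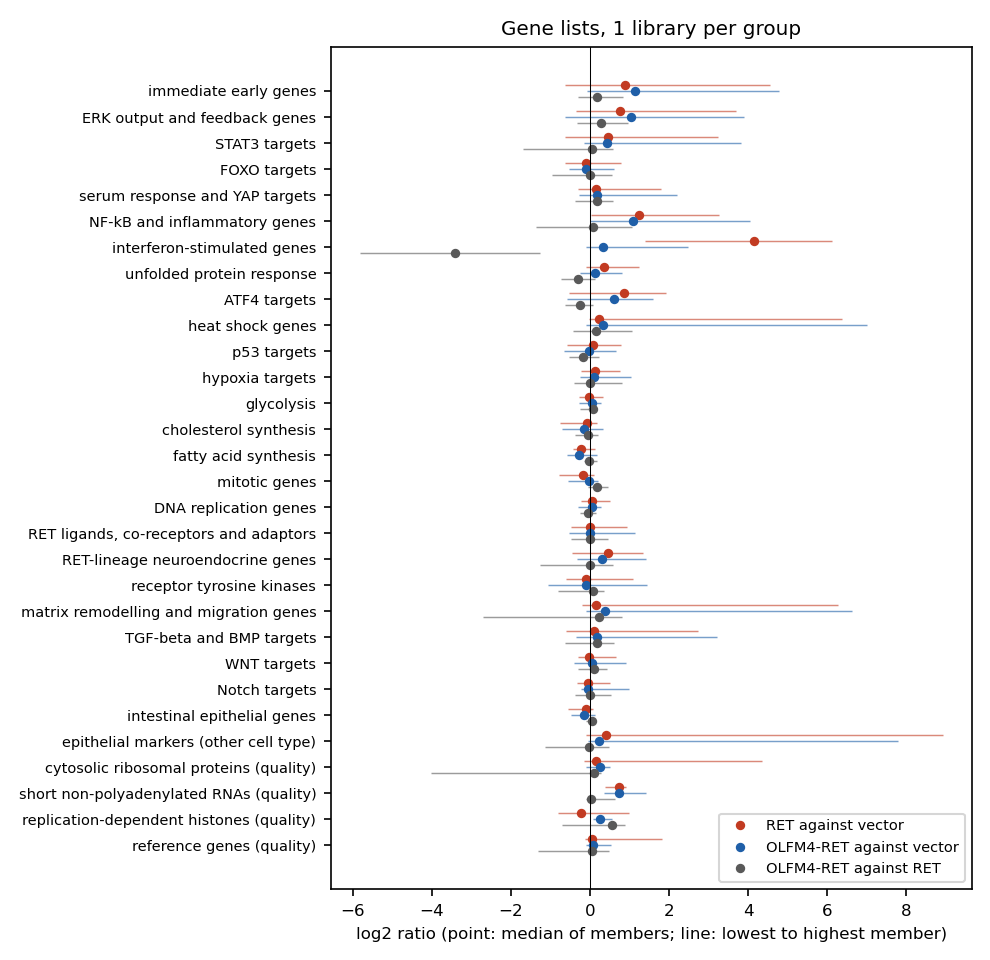
Points show the median log2 ratio of the measured members of each gene list with 5 or more such members in all 3 comparisons. Each group has 1 library, and lines run from the lowest to the highest member. The interferon-stimulated genes lie at 4.14 for RET against vector, 0.32 for OLFM4-RET against vector and -3.42 for OLFM4-RET against RET, while immediate early genes lie at 0.89, 1.15 and 0.19; under total-count scaling the matrix remodelling median for RET against vector turns to -0.02.

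A trend with transcript length was present against the vector library. Over 12853 protein-coding genes, Spearman's rho between log2 ratio and transcript length, across genes that are not independent replicates, was -0.37 for RET against vector, -0.39 for OLFM4-RET against vector and 0.04 for OLFM4-RET against RET. The corresponding values for the GC content of transcripts were 0.06, 0.19 and 0.22. With the length trend removed, 634 genes were higher and 213 lower with RET, and 812 of the genes past the rule were shared with the uncorrected comparison. For OLFM4-RET against vector the counts were 522 and 87, with 579 shared.

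**Figure D3:**
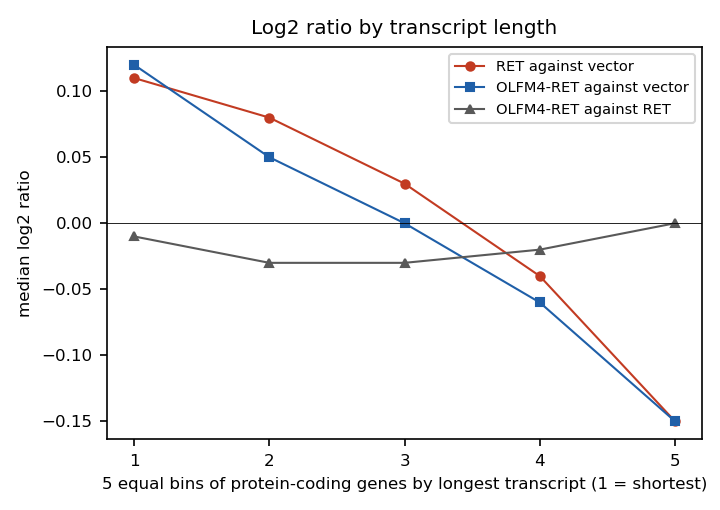
Median log2 ratio in 5 equal bins of 12853 protein-coding genes ordered by their longest transcript, for the 3 comparisons, with 1 line per comparison and 1 library per group. From the shortest to the longest bin the median runs from 0.11 to -0.15 for RET against vector and from 0.12 to -0.15 for OLFM4-RET against vector, and it stays between -0.03 and 0.00 for OLFM4-RET against RET.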

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

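The length correction, the 2 protein-coding restrictions, the removal of overlapping genes and the random lists of protein-coding genes were tests chosen after the results were seen, and the other alternatives were chosen in advance. No paired analysis was possible because each group had 1 library, and for the same reason no library could be left out. Named genes past the size rule kept their direction under every alternative run for them. So did the list medians outside the central 95% of random lists, except that with total counts, a scaling that lowers all ratios against vector, the median of matrix remodelling genes for RET against vector went from 0.15 to -0.02, and those of ribosomal protein genes for RET against vector and of the unfolded protein response for OLFM4-RET against vector came to 0.00. Medians inside those limits carry no direction, and with total counts those of p53 targets (-0.09), hypoxia targets (-0.03), DNA replication (-0.10), TGF-beta and BMP targets (-0.05), RET ligands and adaptors (-0.15) and reference genes (-0.12) for RET against vector turned negative, as did several for OLFM4-RET against vector. Total counts also took members just past 2-fold out of several lists, among them ATF4 targets, receptor tyrosine kinases and the unfolded protein response for RET against vector, and hypoxia targets and RET adaptors for OLFM4-RET against vector, while upper quartile scaling added 1 Notch target for the latter. Other minimums changed the number of members past the rule by at most 3 in each direction of a list, because they change which genes are measured. Some reported medians came back inside the central 95%, among them those of neuroendocrine genes against vector with a minimum of 200 counts (percentiles 89.16 with RET and 94.17 with OLFM4-RET), of matrix remodelling genes for RET against vector (97.21) and of serum response and YAP targets for OLFM4-RET against vector (97.42) with the same minimum, and of ribosomal protein genes for RET against vector without the length trend (85.67). Means in place of medians did the same for neuroendocrine and ribosomal protein genes against vector, for the unfolded protein response with OLFM4-RET against vector and for p53 targets with OLFM4-RET against RET. The number of genes past the size rule followed its own settings, because these change which genes are counted. For RET against vector (861) it was 2127 with a minimum of 10 counts, 422 with 200, 2442 with no minimum, 2139 at 1.5-fold, 264 at 4-fold, 488 with intervals wholly beyond 2-fold and 525 for protein-coding genes. For OLFM4-RET against vector (615) the same settings gave 1655, 265, 2124, 1738, 200, 351 and 400. For OLFM4-RET against RET (342) they gave 974, 198, 1208, 932, 119 and 211, and protein-coding genes gave 236; the split of 102 higher and 240 lower became 524 and 450 with a minimum of 10 counts, 691 and 517 with no minimum and 475 and 457 at 1.5-fold. The number shared by both comparisons against vector (376) was 166 with a minimum of 200 counts, 1056 at 1.5-fold and 113 at 4-fold. Across scalings the totals stayed between 852 and 864, 583 and 630, and 336 and 344. With a change of sign counted only for medians outside the central 95%, 696 list medians stayed close to the reported value under the alternatives, 39 moved and 1 changed sign, and of the log2 ratios of named genes 1049 stayed inside the counting interval and 236 moved outside it. Depth limits the genes at 0 counts in the vector library, for which a ratio is given against the floor, while the lack of replicates limits all of them.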

Other observations

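The gene families of the next paragraph, and every test below except those on blood cell transcripts and on genes with small ratios, were tests chosen after the results were seen.

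Antigen presentation followed the interferon genes. Of 17 measured genes of MHC class I processing, 11 were higher in the RET library than with vector (median log2 ratio 1.41), 0 passed with OLFM4-RET (0.28), and 11 were lower in the fusion library than with RET (-1.16). PSMB9, a subunit of the immunoproteasome that overlaps PSMB8, had 144, 1352 and 171 counts in the vector, RET and fusion libraries, and the peptide transporter gene TAP1 had 4977, 19801 and 5321. Interferon genes themselves were counted, with IFNB1 at 20, 219 and 29 counts and IFNL3 at 6, 228 and 31. Of the measured keratins, 4 of 9 were higher with RET than with vector and 5 of 10 with the fusion, among them KRT17 (1674, 12488 and 8983 counts) and KRT16 (1, 51 and 109) in both. Of 64 measured axon guidance genes, 2 were higher and 3 lower with RET and 3 higher and 1 lower with the fusion. Their medians against vector were -0.20 with RET and -0.21 with the fusion, below all random lists. The trend with transcript length was present in the same comparisons. In all, 10 families were added after the results were seen, not all of them described here, so this rank is a description and not a test.

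Interferon-stimulated genes were higher in the RET library than in either of the others. Blood cells carried over into that sample would bring their abundant transcripts, but the highest of HBB, HBA1, HBA2, LYZ, PTPRC and ITGAM in the RET library was HBA1 with 17.3 normalised counts, against 4239 for CD68, which other cells also express. A swap of the RET and OLFM4-RET labels is excluded by OLFM4, whose count in the RET library was 0.0150% of that in the fusion library. Whether the cells may have responded to the RET plasmid, or to this particular transfection or DNA preparation, cannot be told apart with 1 RET library. As a hypothesis, unfused RET or its plasmid preparation set off an interferon response that the fusion library largely lacked, and repeat transfections with independent DNA preparations would decide it.

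Ratios against vector fell with transcript length. A minority of strongly changed genes did not carry the trend, since among protein-coding genes with an absolute log2 ratio under 0.5 the rho of RET against vector was still -0.36. The rho of OLFM4-RET against RET was 0.04, which is consistent with a property of the single vector library, such as RNA quality or library preparation, and equally with a response to both RET plasmids, so these cannot be told apart. No biological explanation was tested beyond that.

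RPS29 had 7012, 108359 and 7858 counts in the vector, RET and fusion libraries. RN7SL1 lies on the other strand, and its annotated exons overlap those of AL139099.4 but not those of RPS29. The RPS29 count did not follow that of RN7SL1, since its log2 ratio between RET and OLFM4-RET exceeded that of RN7SL1 by 3.90. A shift of a small part of the RN7SL1 reads is not excluded. The RPS29 gain was 119176 normalised counts, against 1970000 for RN7SL1 in the RET library. The 7SL pseudogene RN7SL5P was also highest in the RET library, with 105402, 212565 and 42977 counts. The other 38 ribosomal protein genes had a median ratio of 0.15 against vector and none above 0.36, so a general rise is excluded. The RPS29 pseudogenes together had 0.0271% of the gain as normalised counts in the vector library, too few to have lost reads to RPS29. What could raise this 1 gene in 1 library, such as RPS29 sequence carried with the plasmid DNA or a local transcript, stays open and was not tested.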
